A study of Drosophila melanogaster with 3 samples.

How the data were processed

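ChIP-seq with an antibody against GFP was done on 3 biological replicates of whole embryos from a fly line with GFP-tagged Knirps, aged 0 to 14 h, with chromatin sheared by sonication to 200 to 800 bp, per the labels. The replicate numbers are those of the labels, which call the replicates biological, and all 3 belong to 1 group. The deposited files were peak lists in narrowPeak format, and reads, alignments and coverage tracks were not used here. Per the notes deposited with the samples, the authors called a permissive list of peaks and background for each replicate and for the pooled alignments. All were called against the same control alignment, and the optimal list holds the peaks that passed their threshold on the irreproducible discovery rate. The aligner, the peak caller, their versions and that threshold were not given in the sources used here.

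The deposited signal value of a peak is the authors' own measure of its strength over the control, on a scale that is not stated. It was used only to rank and describe peaks within a list, never to compare levels between lists. The deposited −log10 q value of each peak was used only to describe the lists. In the optimal list 6876 of 7129 peaks share the highest value of 4.14, so it does not rank them. The summit is the deposited offset from the peak start, and an interval may hold several summits, each listed as a peak. Of the optimal peaks, 4793 are 520 bp wide and 6.44% are wider. The optimal list was tested against the pooled list and is exactly the 7129 peaks with the highest signal values in it, so it is a threshold on the pooled signal. The 30000 peaks of each permissive list are a cap. Numbers of reads are not in these files, so depth per replicate is unknown. Intervals on shares cover counting error over peaks only.

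The peak coordinates are those of dm6, whose arms carry the same names and fit within the lengths of Release 6 of the genome in the reference used here. Sequence came from that assembly and genes from Ensembl release 115. Only the arms 2L, 2R, 3L, 3R, 4 and X were used, with 13945 protein-coding genes and 19252 distinct start sites of their transcripts. Noncoding genes were left out of the classes, so intergenic sequence includes them. Coordinates are 1-based. The dm3 lists were used for counts only, because no dm3 genome or annotation was used here, and no coordinate was converted between builds. For 5 gene symbols of the preset lists the name in the annotation differs (hry for h, nanos for nos, stumps for dof, Z600 for frs, ovo for svb).

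A peak was called recovered in a replicate when a summit lay within 100 bp among that replicate's strongest 7129 peaks. Summits were assigned in the order promoter (within 500 bp of a start site), 5' UTR, coding exon, 3' UTR, intron and intergenic, and compared with 1000 circular shifts along each arm. The share of the X was compared with its share of the assembled length by an exact binomial test. Gene lists were compared with 100000 random lists of the same size, matched in 10 quantile bins of territory length, by a two-sided permutation test. Words were counted on either strand within 100 bp of the summit and in a window of the same size 600 bp toward higher coordinates, and compared by an exact McNemar test over peaks. Splits by place and strength used Fisher's exact test. Adjusted values are Benjamini-Hochberg within each family and the threshold was 0.05. These p-values treat peaks or genes as the units, and the spread between embryo samples is given by the SD over 3 replicates. The 20 gene lists and 18 words were written from general knowledge of fly development before the data were examined. The tests and alternatives were also fixed then, unless stated otherwise. The word for Knirps is therefore a simplification of its binding preference.

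The genes named were set by a rule fixed before the data were examined. It takes the 15 peaks with the highest signal value with the nearest start site, and all gap and pair-rule genes. It adds, for each other list, the 3 genes with the strongest peak in their territory and up to 2 without a peak in alphabetical order. It ends with the 10 genes with the most summits and the 10 words of 7 bases with the lowest p. Neighbouring genes that hold a named peak, and the words related to AGAGCA, were named after their values were seen. The result for 1 dense window is not reported here.

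The code was tested on simulated data before use. Of 200 simulated gene lists with no effect, 3% had a p under 0.05, and 97% of 200 lists with raised binding did. In the scan of words of 7 bases, 0 passed before a word was planted, and a word planted in 3% of 7000 windows ranked 1. All 1000 simulated peaks were matched as made. Simulated summit and control windows had the same base frequencies, whereas the real ones had 45.0% and 40.1% G and C. Simulated genes were not clustered. These checks test the code and do not show how often the tests err on the real data. Alternatives changed the definition of a shared peak, the strictness of the list, the promoter and territory widths, the matching, the windows and words, and left out each replicate in turn. Leaving out a replicate means keeping the optimal peaks found in both other replicates. The sets without replicates 1, 2 and 3 hold 4402, 4257 and 4684 peaks, all still called from the pooled replicates. A change in such a set therefore cannot be put down to the replicate left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.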

Results

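Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the genomic sites occupied by Knirps in the fruit fly embryo. Knirps, encoded by the gap gene kni, is a zinc-finger transcription factor of the nuclear receptor family that acts mainly as a repressor in the segmentation of the trunk and later in tracheal development. The embryos carried a transgene for Knirps fused to enhanced green fluorescent protein (GFP), and the fusion protein was pulled down with an antibody against GFP. Whole embryos of both sexes, collected from 0 to 14 h after egg laying, were used in 3 biological replicates that formed 1 group. The design contains no second condition, so the comparisons below set peaks against other positions in the same genome and the replicates against each other. The deposited optimal list held 7129 peaks on genome build dm6, with signal values from 188 to 5038 and a median of 292. Each replicate list and the pooled list held 30000 peaks each, a number that caps the lists rather than measures binding. The numbers of reads behind the lists were not given in the sources used here, so the depth is unknown. An untagged or input sample was not analysed here.

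Each replicate recovered a similar share of the optimal peaks, but few of the weakest were among the strongest 7129 peaks of all 3. Of the 7129 optimal peaks, 77.5% had a summit within 100 bp among the 7129 strongest peaks of replicate 1, 81.1% in replicate 2 and 75.1% in replicate 3, a mean of 77.9% ± 3.03 (SD, n = 3). All 3 replicates held 3712 of the optimal peaks (52.1%), 2207 were found in 2 replicates, 1109 in 1 and 101 in none. Of the 1782 strongest optimal peaks 90.1% were found in all 3 replicates, and of the 1782 weakest 4.32%. The optimal list comes from the pooled replicates, so this recovery is not independent of them. Matched directly, 67.7% of the strongest 7129 peaks of replicate 1 had a summit within 100 bp in those of replicate 2 and 61.4% in those of replicate 3, as had 62.97% of those of replicate 2 in replicate 3. Across peaks matched in both members of a pair, Spearman's rho of the signal values was 0.747 for replicates 1 and 2, 0.675 for replicates 1 and 3 and 0.691 for replicates 2 and 3. These correlations are across peaks, which are not independent replicates. With a summit distance of 50 bp in place of 100 bp, the peaks found in all 3 replicates numbered 2261, with 200 bp 4583 and with any overlap 5055.

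The strongest peaks lay at a small number of loci, several of which held more than 1 of them. The peak with the highest signal value (5038) spanned 13583818 to 13585261 on chromosome arm 2R, in an intron shared by CG6191 and CG45088, and ranked 2, 1 and 1 in replicates 1 to 3. Another 4 of the 15 strongest peaks lay at lower coordinates in the same stretch of 2R. The deposited interval from 13559779 to 13565058 held 3 of them, with summits 2608, 5171 and 6093 bp downstream of the start site of CG13334 and signal values of 2402, 4327 and 2171. The interval from 13579512 to 13580331 lay 5684 bp upstream of CG42808 (2468). On 2L, the interval from 18944064 to 18945106 held summits 484 and 687 bp upstream of ssp3, with signal values of 4913 and 3616. Intergenic peaks also stood 2902 bp upstream of hll (2L, 14023760 to 14024899, 3321) and on either side of Rh5, which encodes an opsin. The Rh5 summits were 667 bp upstream (2L, 12006834 to 12007869, 2587) and 2255 bp downstream (2L, 12009956 to 12012640, 2089) of its start site. The remaining peaks among the strongest 15 were intronic in CG11050 (2L, 6612367 to 6612937, 2305), in cno, which encodes the junction protein Canoe (3R, 5215250 to 5215784, 2300), in sbb (2R, 18336617 to 18337443, 2274) and in gish, a casein kinase gene (3R, 16280002 to 16281501, 2251). The last was intergenic, 87 bp upstream of CG14100 (3L, 19590421 to 19590813, 2191). The lowest rank of any of these 15 peaks in a replicate was 34.

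Summits were concentrated at transcription start sites and were rare in coding exons. A share of 37.0% of the optimal summits (2639 of 7129, 95% Wilson interval 35.9% to 38.1%) lay within 500 bp of the start site of a protein-coding transcript, against 11.5% ± 0.592 (SD over 1000 shifts) when the summits were shifted along each chromosome arm. The share in the replicates' strongest 7129 peaks was 37.2% ± 2.22 (SD, n = 3). Against comparisons chosen after the data were seen the excess was smaller, with 14.1% for shifts of 10 to 50 kb and 22.5% for the 22871 pooled peaks ranked below the optimal list. Outside promoters, coding exons held 0.449% of the summits against 13.9% of the shifted positions, 3' UTRs held 0.884% against 4.44% and intergenic sequence 19.96% against 30.1%. These 4 classes, promoters included, differed from the shifted positions with an adjusted p of 0.0015 (two-sided permutation of positions, Benjamini-Hochberg over 6 classes), which rests on the smallest p that 1000 shifts can give. Introns held 40.7% of the summits, close to the 39.2% of shifted positions (adjusted p = 0.214 by the same permutation test). The share in 5' UTRs, 1.04% against 0.782%, passed the threshold (adjusted p = 0.0288, permutation test), but among the 4257 optimal peaks found in both replicates other than replicate 2 it was 0.987% with an adjusted p of 0.186 by permutation. Its adjusted p under the alternatives ran from 0.0216 to 0.186.

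**Figure D1:**
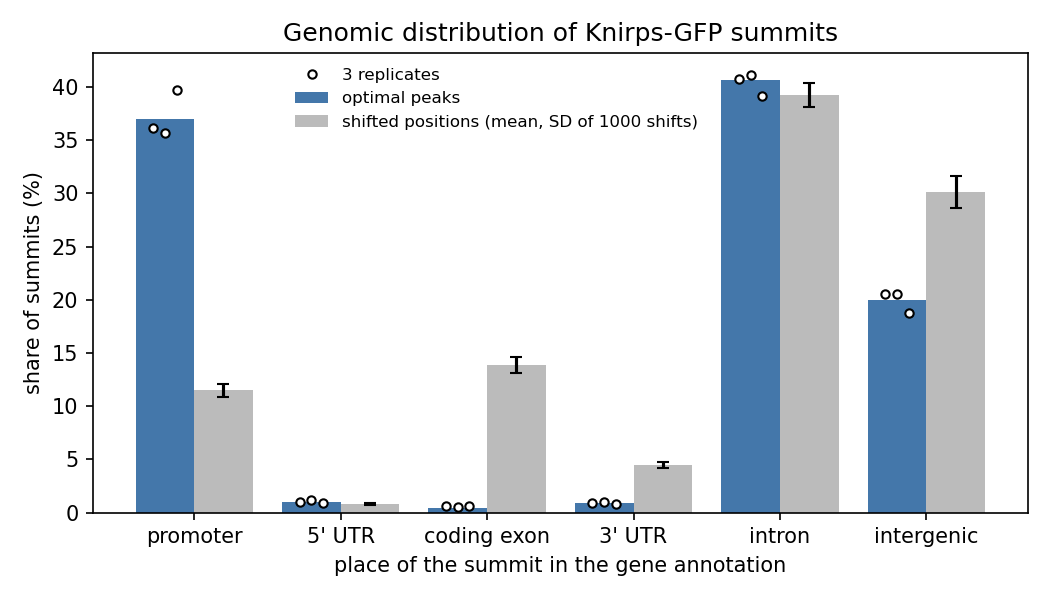
Share of summits (%) in 6 annotation classes, in order of priority from left to right. Blue bars are the 7129 optimal peaks, open circles the strongest 7129 peaks of each of the 3 replicates, and grey bars the mean of 1000 shifts of the summits along the arms with the SD. Promoter summits made up 37.0% of the optimal peaks and 11.5% of the shifted positions, and coding exons 0.449% and 13.9%.

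The X chromosome and chromosome 4 carried fewer summits than their lengths. The X held 1002 of the optimal summits (14.1%, Wilson interval 13.3% to 14.9%) on 17.6% of the assembled length of 6 arms (p = 9.31e-16, exact binomial test, two-sided). The replicates gave 14.2%, 13.8% and 14.6%. The deficit was not seen in the 22871 pooled peaks ranked below the optimal list, of which 18.04% lay on the X. Embryos of both sexes were used, and the copy number of the X was not taken into account in these comparisons. Chromosome 4 held 26 summits (0.365%) on 1.01% of the length (adjusted p = 2.22e-09 over the 6 arms, exact binomial test). Arm 3L held 22.7% of the summits (Wilson interval 21.8% to 23.7%), more than its share of the length (adjusted p = 6.94e-04, exact binomial test). Arms 2R (adjusted p = 0.0274) and 3R (adjusted p = 0.0353) were slightly above theirs by the same exact test, and 2L did not differ (adjusted p = 0.618). Summits on an arm are not independent of one another, so these p-values are too small by an unknown amount. The X carried 17.01% of the protein-coding start sites, also more than its share of summits (p = 1.18e-11, exact binomial test, a comparison added after the data were seen).

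Among the gap genes, kni itself and its paralog knrl carried the strongest peaks. In what follows, the territory of a gene is its body with 5 kb on either side. The territory of kni (FBgn0001320, 3L, 20692330 to 20695378) held 8 optimal summits, and those of the replicates 7, 7 and 8. The strongest, from 20690961 to 20691885, had a signal value of 988, ranked 170 of 7129 and lay 3110 bp downstream of the start site of kni, past its 3' end. A stronger peak (20621563 to 20622182, signal value 1682, rank 30) stood 1203 bp upstream of knrl (FBgn0001323, 3L, 20597141 to 20620659), a related nuclear receptor gene, whose territory held 4 summits. From 20590 to 20720 kb of 3L there were 33 optimal summits, most of them between the genes CG13251 and cmpy, on either side of kni. The extent and copy number of the tagged transgene were not given in the sources used here. Extra copies of the kni locus therefore cannot be told apart from binding there. The other gap genes had weak peaks or none. The genes hkb (rank 4719, 235 bp upstream), Kr (rank 5706, 814 bp upstream) and tll (rank 6470, 217 bp upstream) had 1 summit each, with signal values of 246, 219 and 202. Each of these summits was missing from the peaks found in both other replicates when replicates were left out, for hkb without replicate 2 or 3, for Kr without replicate 1 or 2 and for tll without replicate 1 or 3. No optimal summit lay in the territory of gt or hb, whose best peaks in the pooled list ranked 18722 and 19959 of 30000. Each sample mixed embryos from the whole age range, and stages were not separated. A weak or missing peak therefore cannot be told from binding limited to a short stage.

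**Figure D2:**
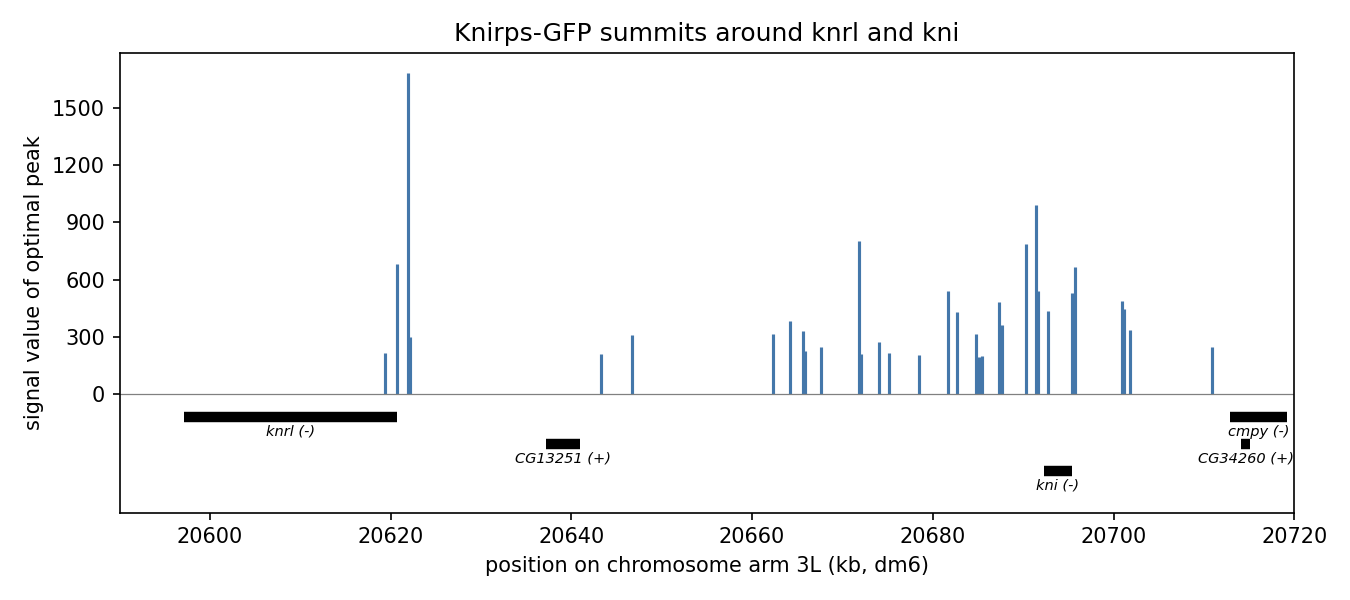
Optimal peaks from 20590 to 20720 kb of chromosome arm 3L on dm6. Each vertical line is a summit with its deposited signal value, and black bars are protein-coding genes with their strand. The highest of the 33 lines (1682) stands next to knrl, and a run of summits extends from the right of CG13251 to beyond kni.

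Pair-rule genes, a class of segmentation genes, were bound unevenly. The nuclear receptor gene ftz-f1 held 13 summits in its territory, the strongest in an intron (3L, 18771369 to 18772286, signal value 799, rank 332). The repressor gene hry, known as hairy, held 4, the strongest 112 bp upstream of its start site (3L, 8675467 to 8675862, signal value 673, rank 536). The paired forkhead genes slp1 and slp2 held 3 each, with signal values of 483 and 512 at their strongest. The gene run (363) had 1 summit, opa (320.3) had 2 and odd (199) had 1. Among the peaks found in both other replicates, ftz-f1 held 7 without replicate 1 and 6 without replicate 2, and hry held 2 without replicate 2 or 3. The summits of run and odd were lost without replicate 1 or 2. No optimal summit lay in the territories of eve, ftz or prd, and their best pooled peaks ranked 7962, 10648 and 23835. As for the gap genes, binding limited to a short stage could be missed in embryos of mixed age. Summits were present for 5 of 7 gap genes against 3.53 expected from random lists matched on gene length (adjusted p = 0.593), and for 7 of 10 pair-rule genes against 4.97 (adjusted p = 0.342, both by permutation test). Both lists did pass with the gene of the nearest start site (adjusted p = 0.0234 for gap and 0.00103 for pair-rule genes, permutation test), and under 2 other alternatives each. Over all alternatives the adjusted p ran from 0.0234 to 1 for gap genes and from 0.00103 to 0.639 for pair-rule genes.

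Across 20 preset gene lists, 3 had summits more often than length-matched genes and 1 less often. Among all 13945 protein-coding genes of the 6 arms, 45.4% had an optimal summit in their territory. The test drew 100000 random lists per gene list, matched on territory length, and was two-sided with Benjamini-Hochberg adjustment over the 20 lists. It treats genes as independent, so it says nothing of the spread between replicates. Head patterning genes had a summit in 8 of 8 cases against 3.98 expected (p = 0.00308, adjusted p = 0.0154, permutation test), and 7.67 ± 0.577 in the replicates (SD, n = 3). The strongest of them lay near slp2 and slp1, followed by ems, a homeobox gene of the head (3R, 13909040 to 13909404, signal value 451). Their call ended with a territory of 10 kb (adjusted p = 0.186, permutation test) and among the 3564 strongest peaks, 6 of 8 (adjusted p = 0.0644, permutation test). Over all alternatives their adjusted p ran from 6.55e-06, by an exact test, to 0.186. The number of lists above matched genes fell to 2 with a territory of 10 kb and rose to 8 with a territory of 2 kb, to 11 with the gene of the nearest start site and to 9 without length matching. It was 6 among optimal peaks found in both others without replicate 1, 7 without replicate 2 and 4 without replicate 3.

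All 10 genes of the Enhancer of split complex, the clustered targets of Notch signalling, had a summit, against 3.26 expected (adjusted p = 6.67e-05, permutation test), and all 10 in each replicate. Their territories overlap and share 41 distinct summits, so they are not 10 independent cases. The strongest, on 3R from 26005874 to 26007084 (signal value 1647, rank 32), lay 351 bp upstream of E(spl)mbeta-HLH and also within 5 kb of E(spl)malpha-BFM. The next (26002219 to 26003394, signal value 1238) lay downstream of both E(spl)mdelta-HLH and E(spl)mgamma-HLH.

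Ribosomal protein genes formed the largest list above expectation, with a summit in 71 of 92 against 35.2 expected (adjusted p = 6.67e-05, permutation test) and 70.3 ± 3.21 in the replicates (SD, n = 3). In 62 of the 92 a summit lay within 500 bp of the gene's own start site. RpS27 had its strongest summit 1 bp upstream of its start site (3R, 25247326 to 25247726, signal value 1567) and RpL7 had it 40 bp downstream in the 5' UTR (2L, 10200860 to 10201210, signal value 1259). The strongest peak in the territory of RpL22 (X, 758757 to 759476, signal value 1497) lay 6112 bp from its start site and nearer to CG5273. No summit was found for RpL10 and RpL10Aa, among 21 such genes. Proteasome genes, a list of subunit genes and 16 paralogs of them, had a summit in 19 of 48 against 18.7 expected (adjusted p = 1, permutation test). Peaks in the territories of Prosbeta2R2, Prosalpha3 and Rpt5 lay in introns of the neighbours cno, CG10543 and Hrd3, with signal values of 2300, 1498 and 895. Prosalpha1 and Prosalpha1R had none. When each summit was given only to the gene of the nearest start site, 1 proteasome gene was left, below matched genes (adjusted p = 0.027, permutation test). Over all alternatives the adjusted p of this list ran from 0.013, by an exact test, to 1.

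Odorant and gustatory receptor genes, which serve adult smell and taste, had a summit in 19 of 119 against 48.8 expected (adjusted p = 6.67e-05, permutation test) and 20.7 ± 2.89 in the replicates (SD, n = 3). Many of these genes are clustered. The strongest peaks in their territories lay in an intron of Tre1 beside Gr5a (1229), 867 bp upstream of Or88a (1042) and 3104 bp downstream of Or85f near RpL34b (809). Gr10a and Gr10b were among the 100 without a summit. Chorion and yolk protein genes, which are expressed in adult females, had a summit in 1 of 12, near Yp3, against 4.49 expected (adjusted p = 0.147, permutation test), with none at Cp15 or Cp16. They fell below other genes without length matching (adjusted p = 0.0176, Fisher's exact test) and when matched on start sites, in a range from 0.0176 to 0.48 over all alternatives. Muscle structural genes had 4 of 12 against 6.90 (adjusted p = 0.24, permutation test). They fell below matched genes, with 1 of 12, without replicate 2 (adjusted p = 0.0424) and without replicate 3 (adjusted p = 0.018, both by permutation test), in a range from 0.018 to 0.745 over all alternatives. Tm1, Mlc2 and wupA were among the 4, with signal values of 945, 238 and 226 (the last pair in 5' UTRs of the neighbours Rsod and Mvb12), and Act87E and bt were among the 8 without a summit.

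**Figure D3:**
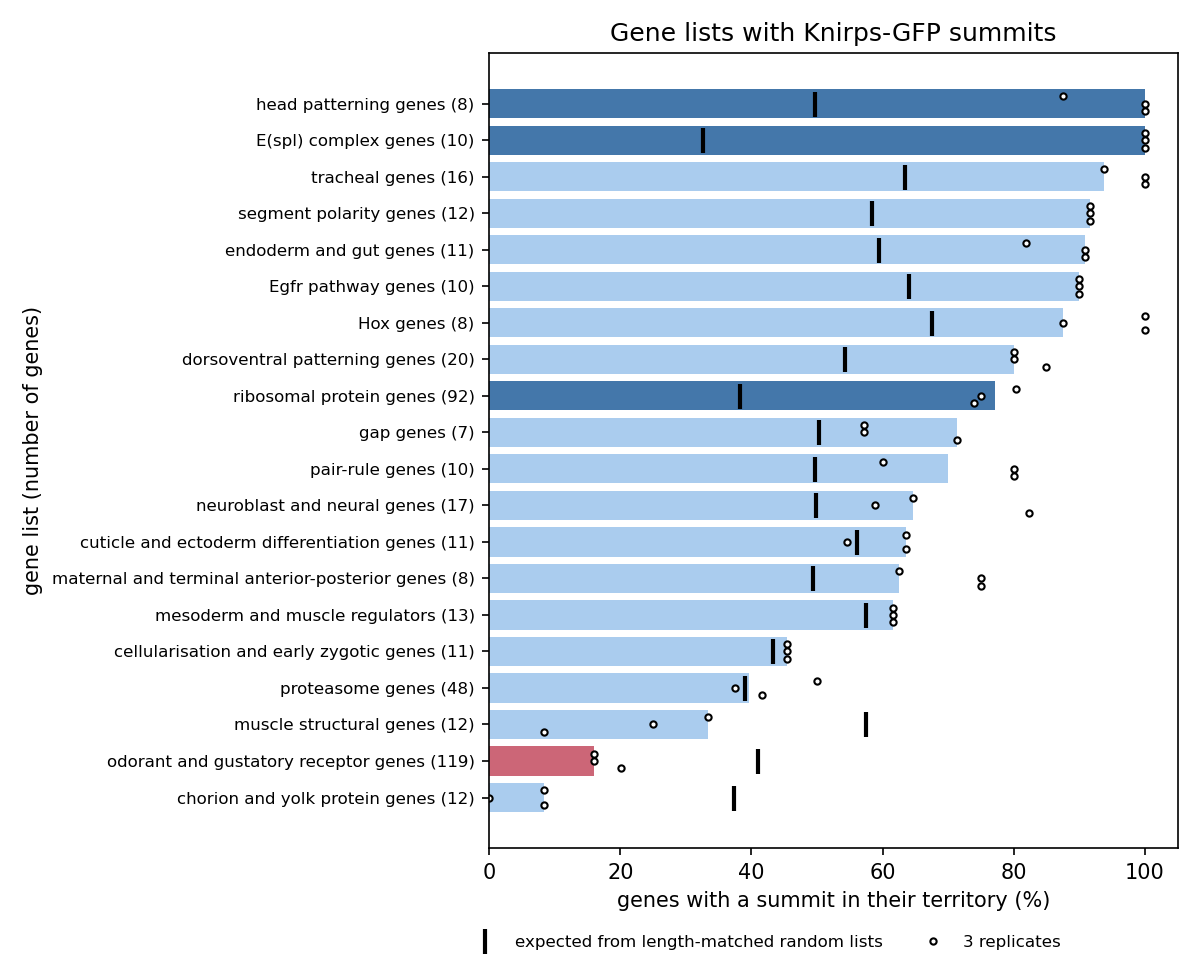
Percentage of genes in each of 20 lists with an optimal summit in the gene body or within 5 kb of it, with list sizes in parentheses. Dark blue bars were above and the red bar below random lists matched on length (black ticks) at an adjusted p under 0.05, pale bars passed in neither direction, and open circles are the 3 replicates. Ribosomal protein genes stand at 77.2% and receptor genes at 16.0%.

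Most lists of developmental regulators lay above expectation without passing the threshold. Tracheal genes had a summit in 15 of 16 cases against 10.1 expected (adjusted p = 0.0584, permutation test). The list passed among the 3564 strongest peaks, where 15 genes again had a summit (adjusted p = 4.00e-04, permutation test), and without each of the replicates in turn. Its adjusted p over the alternatives ran from 2.75e-08, by an exact test, to 0.229 with a territory of 10 kb. Apart from knrl and kni, its strongest peak was intronic in rib, a gene required for tracheal branching (2R, 19271568 to 19272279, signal value 989), while salr had none. Segment polarity genes had 11 of 12 against 7.02 (adjusted p = 0.0928, permutation test). They were led by ci, the transcription factor of Hedgehog signalling, with a summit 132 bp upstream of a start site (4, 56190 to 56660, signal value 1371), and then by ptc (829.5) and nkd (542). The gene gsb had none. Dorsoventral patterning genes had 16 of 20 against 10.9 (adjusted p = 0.0636, permutation test). The strongest peak in the territory of ush, a cofactor of GATA factors, had a signal value of 1584 but lay in the 3' UTR of the neighbour lwr, and twi (675) and sog (639.7) followed. There was none for scw or tld. Both lists passed among the optimal peaks found in both others without replicate 1 or 2. Segment polarity genes then had 10 (adjusted p = 0.0491 and 0.0424, permutation test) and dorsoventral genes 14 (adjusted p = 0.0494 and 0.0442, permutation test). Over all alternatives the adjusted p ran from 1.2e-04 to 0.112 for the former and to 0.2496 for the latter.

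Endoderm and gut genes had a summit in 10 of 11 against 6.53 expected (adjusted p = 0.139, permutation test). The peak 247 bp upstream of fkh, a forkhead factor gene of the gut and salivary glands (3R, 28585166 to 28585876), had a signal value of 1715 and ranked 28, and bowl (1352) and grn (619) followed, while lin had none. The list passed with a territory of 2 kb (adjusted p = 0.0221, permutation test) and 4 other alternatives, in a range from 6.00e-04 to 1. Egfr pathway genes had 9 of 10 against 6.40 (adjusted p = 0.206, permutation test). S, which encodes the ligand chaperone Star, held a peak of 1195, the ligand gene spi 1040 and the repressor gene aop 954, and kek1 had none. The list passed without replicate 2 (adjusted p = 0.0473, permutation test), with the gene of the nearest start site (adjusted p = 0.0165, permutation test) and under 3 other alternatives, in a range from 1.2e-04 to 0.547 over all alternatives. Hox genes had 7 of 8 against 5.40 (adjusted p = 0.409, permutation test), with intronic or upstream peaks of 767 at abd-A, 688 at Antp and 578 at Ubx and none at pb. The list passed without length matching (adjusted p = 0.0493, Fisher's exact test) and 2 other alternatives, in a range from 1.2e-04 to 0.722. Neuroblast and neural genes had 11 of 17 against 8.47 (adjusted p = 0.342, permutation test). A peak of 1447 stood 263 bp upstream of elav, which encodes a neuronal RNA-binding protein, and grh (851) and SoxN (639.9) followed, with none at ac or ase. The list passed with a territory of 2 kb (adjusted p = 0.0463, permutation test) and 2 other alternatives, in a range from 0.0251 to 1.

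The remaining lists lay close to expectation. Mesoderm and muscle regulators had a summit in 8 of 13 against 7.47 (adjusted p = 0.873, permutation test). The peak of 1615 in the territory of Mef2 lay in an intron of the neighbour Pal1, and twi and bin (608) followed, while bap and htl had none. Maternal and terminal genes of the anterior-posterior axis had 5 of 8 against 3.96 (adjusted p = 0.616, permutation test), with peaks of 629 in pum, 449.9 near osk and 415 in cad and none at tor or trk. Cuticle and ectoderm differentiation genes had 7 of 11 against 6.16 (adjusted p = 0.873, permutation test). Peaks of 484, 381 and 332 stood in the territories of ovo, f and kkv, with none at Ddc or sha. Cellularisation and early zygotic genes had 5 of 11 against 4.77 (adjusted p = 1, permutation test), with peaks of 843, 651 and 464 in the territories of Z600, Sry-alpha (nearer to RpL32) and trbl and none at bnk or halo.

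The 10 genes with the most summits held from 20 to 30 each. The territory of Eip75B, an ecdysone-induced nuclear receptor gene (3L, 17950953 to 18064696), held 30 optimal summits, and 29, 35 and 34 in the replicates. It was followed by jing (29), a zinc-finger gene with a role in tracheal cells, by tara and CG1677 (25 each) and by sbb, CG46467 and Glut4EF (23 each). The last 2 genes overlap and share their summits. EcR, the ecdysone receptor gene, and hth, a Hox cofactor gene, held 21 each, and fz2, a Wnt receptor gene, held 20. Of these 10 genes, the highest signal value was 2274 in sbb and the next 1645, at 132 bp upstream of a start site of tara. These counts are not corrected for gene length, which ran to 132008 bp in hth.

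The sequence word taken for Knirps was not enriched at the summits of the optimal peaks, whereas GA-rich words and the words of several other factors were. The Knirps word TAGAGCA lay within 100 bp of the summit in 125 of 7129 peaks (1.75%, Wilson interval 1.47% to 2.09%). It occurred in 119 of the windows of the same size centred 600 bp away, a ratio of 1.05 (p = 0.747, adjusted p = 0.896, exact McNemar test, Benjamini-Hochberg over 18 words). In the replicates' own lists the ratio was 1.19 ± 0.179 (SD, n = 3). It passed the threshold in replicate 2 (ratio 1.40, adjusted p = 0.0255, exact McNemar test) and not in replicates 1 and 3 (1.09 in each, adjusted p = 0.629 and 0.614). The shorter word AGAGCA gave a ratio of 1.45 (p = 4.90e-16, exact McNemar test) and the longer CTAGAGCA 1.69 (p = 0.175, exact McNemar test). The word of GAGA factor, GAGAGAG, had a ratio of 2.85, with 737 summit windows against 259 control windows, and 2.83 ± 0.0552 in the replicates (SD, n = 3). Ratios of 2.92 for the GA repeat word GAGAGCG, 2.87 for the Grainyhead word AACCGGTT and 2.74 for the DREF word TATCGATA were of similar size. Ratios were 1.59 for the Zelda word CAGGTA and 1.46 for CAGCTG, an E-box. The largest adjusted p among these 6 words was 1.12e-05. Of these 6, only GAGAGAG was compared with words that have the same count of G or C bases. The Bicoid word TAATCC was depleted, with a ratio of 0.603 (adjusted p = 8.23e-13, exact McNemar test) and 0.600 ± 0.0297 in the replicates (SD, n = 3). Summit windows were richer in G and C than control windows. The Bicoid word was not compared with words of like composition, so composition stays open as a source of its depletion. The words taken for Kruppel, Hunchback, Caudal, Giant, Tailless, Twist, Snail, Stat92E, Tinman and GATA factors had ratios from 0.732 to 1.29 and did not pass. In the replicates' own lists, Hunchback (0.792) and Caudal (0.829) were lower in replicate 3 (adjusted p = 0.0219 and 0.0211, exact McNemar test) and Twist (1.27) higher in replicate 2 (adjusted p = 0.0281, exact McNemar test). Twist also passed among the optimal peaks left without replicate 3 (ratio 1.40, adjusted p = 0.0112, exact McNemar test), and within 250 bp of the summit (adjusted p = 0.0495, exact McNemar test), in a range from 0.0112 to 0.783 over all alternatives. Among the strongest 500 peaks, a set chosen after the data were seen, Zelda, GAGAGAG and GAGAGCG passed, DREF, CAGCTG and Bicoid did not, and the Grainyhead word was in 0 summit and 2 control windows.

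**Figure D4:**
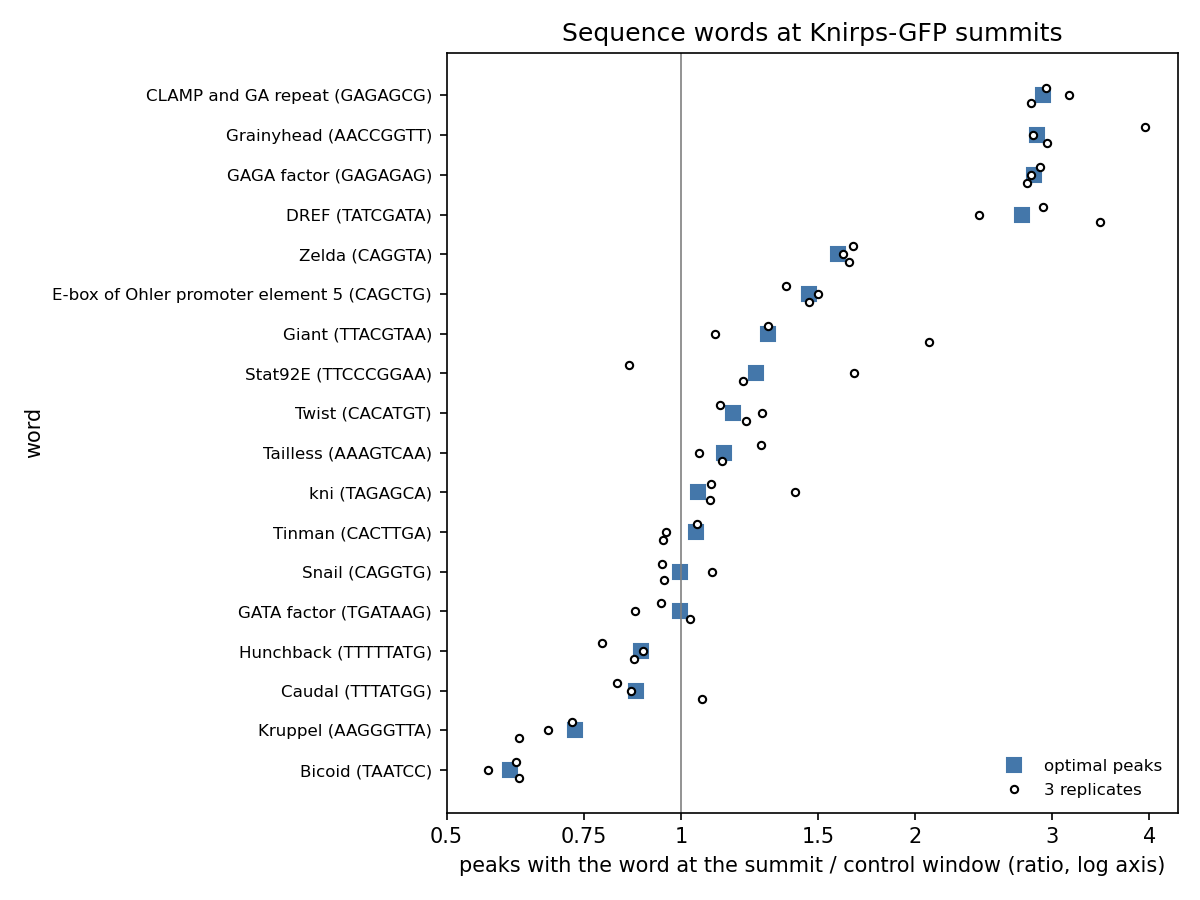
Ratio of peaks with a word within 100 bp of the summit to peaks with it in the control window, on a log axis, for 18 words. Squares are the 7129 optimal peaks and open circles the strongest 7129 peaks of each of the 3 replicates. The GAGA factor word stands at 2.85, the Knirps word at 1.05 and the Bicoid word at 0.603.

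A scan of all words of 7 bases, merged with their reverse complements, made no choice of factor. At an adjusted p under 0.05, 1649 words were more frequent at summits and 1445 less frequent. The lowest p-values belonged to CACACAC (1215 against 556 peaks, ratio 2.19, adjusted p = 1.86e-60, exact McNemar test), CTCTCTC (ratio 2.85), CTCGCTC (3.02) and CGCTCTC (2.92). ACACACA (1.95), AGAGAGC (2.79), CGCACAC (2.37), CTCTCGC (3.15), AGAGAGA (2.47) and AGAGCGA (2.68) completed the leading 10, all of them CA or GA repeats and their relatives. TAGAGCA ranked 7238 by p. Other words that contain AGAGCA ranked higher, with ratios of 2.06 for GAGAGCA, 1.66 for CAGAGCA and 1.21 for AAGAGCA. The windows at summits were richer in G and C, with 44.8% ± 0.534 in the replicates against 40.3% ± 0.244 in the control windows (SD, n = 3). Among the 4257 optimal peaks found in both replicates other than replicate 2, 1032 words were more frequent, and among the 3564 strongest peaks 982.

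Words differed between promoter and distal summits and between strong and weak peaks. The Knirps word was present at 1.58% of the 4490 distal summits and 2.05% of the 2639 promoter summits (odds ratio 0.769, adjusted p = 0.242, Fisher's exact test over 18 words). The difference passed the threshold only when promoters were widened to 1000 bp (odds ratio 0.642, adjusted p = 0.0464, Fisher's exact test), in a range from 0.0464 to 0.844 over the alternatives. DREF words were at 3.18% of promoter summits and 0.267% of distal ones (adjusted p = 1.31e-23, Fisher's exact test). GAGAGAG was also more frequent at promoters (13.2% against 8.66%, adjusted p = 2.03e-08 by the same exact test), as were GAGAGCG and CAGCTG. Distal summits more often had the words of Caudal (5.90% against 3.71%, adjusted p = 1.57e-04 by the same exact test), Twist, Zelda and Tinman. Between the 1782 strongest and the 1782 weakest optimal peaks, the Knirps word was at 1.96% and 1.35% (odds ratio 1.47, adjusted p = 0.566, Fisher's exact test). GAGAGAG was at 13.7% and 8.25% (adjusted p = 2.13e-06) and GAGAGCG at 12.9% and 6.85% (adjusted p = 2.62e-08, both by the same exact test), and no other word passed. AGAGCA in place of the Knirps word did pass (odds ratio 1.32, adjusted p = 0.0268, Fisher's exact test), and without replicate 3 the odds ratio of the Knirps word was 0.927. Over the alternatives the adjusted p ran from 0.0268 to 1.

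The older build gave a shorter optimal list. On dm3 the deposited optimal list held 6614 peaks, 92.8% of the number on dm6. Every arm had fewer, from 1664 against 1787 on 3R to 20 against 26 on chromosome 4, and the X held 923 against 1002. The share on the X was 14.0% on dm3 and 14.1% on dm6. Only 1 dm3 peak lay outside the 6 arms. Peak positions were not compared between builds.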

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

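The word counts in the lower-ranked peaks, the comparison of the GAGAGAG word with words of like composition and both tests of the ribosomal protein genes, as well as the counts of the forms of AGAGCA, were chosen after the results were seen.

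The words of several factors were also enriched in 22871 pooled peaks that rank below the optimal list and that the comparisons of words did not use. Ratios of summit to control windows were 2.34 for the Grainyhead word, 1.83 for GAGAGAG, 1.73 for GAGAGCG and 1.71 for the DREF word. They were 1.32 for CAGCTG, 1.23 for the Twist word, 1.17 for the Zelda word and 1.13 for the Snail word. Each passed an adjusted p of 0.05 by an exact McNemar test, which drew attention to them as a signal in data outside the main list. They were not compared with words of like base composition in those peaks, so composition stays open as a source of these ratios. The Knirps word had a ratio of 1.08 there (adjusted p = 0.401, exact McNemar test).

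GA-rich words were enriched at the optimal summits and the Knirps word TAGAGCA was not. The GAGAGAG ratio of 2.85 lay at percentile 99.96 of the ratios of 2240 words with 4 G or C bases, whose 95th percentile was 1.73. The scan had already ranked this word 10 by ratio, so a place above that percentile was known beforehand. Most words with as many G or C bases had lower ratios, but other features of base composition were not matched and stay open as a cause. For TAGAGCA the ratio of 1.05 lay at percentile 64.2 of words with 3 G or C bases, whose 95th percentile was 1.45. An enrichment hidden by composition was set to need a ratio above that percentile, so a large one is argued against. A small one cannot be excluded, since the median of those words was 0.965. Whether GA repeats account for the enrichment of AGAGCA cannot be told: in 3518 peaks with GAGAG in neither window its ratio was 1.09 (p = 0.297, exact McNemar test), but the form CAGAGCA, picked for its own enrichment, kept a ratio of 1.49 there (p = 0.00487, exact McNemar test), and the forms that hold no GAGAG had 1.29 in all peaks; the rule for this reading was changed after these values were seen. An untagged control was not analysed here, so pull-down at open GA-rich chromatin stays open, and no biological explanation was tested, since the design gives no other group.

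Ribosomal protein genes had summits more often than matched genes, and proteasome genes did not. Start sites of neighbouring genes are argued against as the whole cause, since the ribosomal list stayed above random lists matched on start sites (adjusted p = 1.00e-04, permutation test, from the smallest p that the permutations can give). Of 32 proteasome genes, with 16 paralogs named R or T left out, 2 had a summit at their own start site. This share was 6.25% (exact interval 0.766% to 20.8%), below the 67.4% of ribosomal protein genes (56.8% to 76.8%). At the rate of all protein-coding genes, 5.89 of the 32 would have one (p = 0.106, Fisher's exact test). Pull-down alike at the start sites of both lists is argued against. The counts at own start sites had been seen when this comparison was set, and other broadly transcribed genes were not compared. Pull-down at broadly transcribed genes in general therefore cannot be decided from it. Pull-down that grows with the level of transcription stays open, since neither expression nor an untagged control was analysed here. No biological explanation was tested, since the design gives no other group.

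Optimal peaks were dense around kni, with 22 summits in a window of 50 kb, a number that 25 protein-coding genes (0.179%) reach. Extra copies of the locus from the tagged transgene could raise reads there. The coding exons of kni held 1 pooled summit, where at least 3 would have counted for this explanation and 0 against it, so it cannot be told apart from binding. The extent of the transgene was not given in the sources used here, and no biological explanation was tested, since the design gives no other group.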

How the results depend on the processing

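Comparisons with lower-ranked peaks, local shifts and the share of start sites, matching on start sites, the gene's own promoter, the strongest 500 peaks, windows of 250 bp and the sets without peaks wider than 520 bp were chosen after the data were seen. The promoter share, the X share and the E(spl), ribosomal protein and receptor lists kept their direction and call under every alternative run for them. Enriched words numbered 6, and 7 with Twist without replicate 3 and within 250 bp. Among the strongest 500 peaks Zelda, GAGAGAG and GAGAGCG passed, DREF (adjusted p = 0.281), CAGCTG (0.254) and Bicoid (0.065) kept their direction without passing, and Grainyhead reversed to a ratio of 0 (0.808, all by exact McNemar test), with fewer peaks tested. The cause of the changes below was not tested.

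Recovery in the replicates was 65.4% at 50 bp, 84.8% at 200 bp, 87.7% with any overlap, 73.7% with reciprocal overlap, 93.6% for the stronger 3564 peaks and 93.4% in whole lists. Peaks in all 3 replicates numbered 2261 at 50 bp, 4583 at 200 bp and 5055 with any overlap, and the mean rho was 0.653 among the stronger peaks.

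Lists above matched genes numbered 8 at 2 kb, 2 at 10 kb, 11 by nearest start site, 9 unmatched, 12 matched on start sites, 11 by own promoter and 4 to 7 without a replicate. Lists that changed side of expectation were cuticle (5 genes at 2 kb, 7 at 10 kb, 3 by nearest start site and 3 among stronger peaks), maternal (5 at 10 kb, 1 by nearest start site and 1 by own promoter) and cellularisation (5 at 10 kb). So did the gap (2) and neural (3) lists among stronger peaks, and the proteasome list with 1 by nearest start site, 19 unmatched, 19 matched on start sites and 2 by own promoter. Without a replicate the proteasome list had 13 to 14 genes, below expectation without replicate 2 or 3 and above it without replicate 1.

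Word ratios that crossed 1 were Tinman (0.953 within 50 bp, 0.892 among stronger peaks), Snail (1.03 with the left control, 1.02 without wide peaks), Stat92E (0.556 with the left control) and GATA (1.01 without wide peaks). Among the strongest 500 peaks Kruppel (2.5) and Hunchback (1.07) rose above 1 and Tinman (0.941) fell below it. Within 250 bp Tinman did so too (0.978). Without a replicate, Snail ran from 0.966 to 1.04, above 1 without replicate 1 or 3, and Stat92E from 0.667 to 4, below 1 without replicate 2. The Knirps word had a ratio of 1.45 as AGAGCA and 1.69 as CTAGAGCA (22 against 13 peaks, p = 0.175, exact McNemar test). Its distal odds ratio was 0.642 at 1000 bp, and its odds ratio for strength 1.32 as AGAGCA and 0.927 to 1.43 without a replicate, reversed without replicate 3. Enriched words of 7 bases numbered 982 among stronger peaks and 1032 to 1289 without a replicate, with fewer peaks tested. The dm3 list was 100% of the dm6 number for whole lists, which are capped. The X share was not run on dm3, whose arm lengths were not used here. Depth is unknown, so its limits could not be set.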

Other observations

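The windows and gene classes here were chosen after the data were seen. Among windows of 50 kb, the densest held 41 optimal summits and lay over the E(spl) complex and gro (3R, 25995001 to 26045000), with 38.3 ± 1.15 summits in the replicates (SD, n = 3). The next, on 2R from 13535001 to 13585000 over CG13334, CG42808 and CG6191, held 28, of which 7 were among the 100 strongest. Windows around kni held 26, around aop 25 and around tara 25. A window over CG1677 (X, 7290001 to 7340000) held 24 and another over Eip75B 23. The windows over lola and psq and on 2L from 14430001 to 14480000 held 22 each. The median window held 1.

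Genes for small nuclear RNAs had an optimal summit within 500 bp in 11 of 32 cases against 1.74 in shifted positions (adjusted p = 0.002, permutation of positions, 8 classes), and in 9.67 ± 3.06 in the replicates (SD, n = 3). Genes of the annotation class ncRNA had one in 484 of 3261 against 270.5 (adjusted p = 0.002, permutation of positions). The separate class of tRNA genes had one in 29 of 290 against 14.5 (adjusted p = 0.012, permutation of positions). Genes for snoRNA (23 of 269 against 13.6, adjusted p = 0.158) and rRNA (0 of 99 against 5.24, adjusted p = 0.523) did not pass by the same permutation. Annotated transposable elements had one in 114 of 5809 against 510.1 (adjusted p = 0.002, permutation of positions). The shifted positions took no account of where reads can be mapped in repeated sequence, so this deficit cannot be told from lost mapping.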
